A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

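The series holds 2-colour spotted arrays of budding yeast RNA. On each of the 16 arrays, RNA of 1 strain was set against RNA of a reference pool, with the dyes exchanged between the arrays lettered a (strain in Cy3) and b (strain in Cy5). Per the labels and protocols, strains were grown to mid-log phase in a plate reader, strain and reference RNA were isolated by different protocols, and both were amplified with T7 RNA polymerase together with external control RNA before labelling. The reference pool is not stated to be wild type.

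The raw scanner files hold, per the file headers, mean spot intensity and median local background intensity for each channel, which the authors deposited without background subtraction or normalisation. The deposited matrix holds log2 ratios that the authors normalised to total mRNA per the series description. Its values were set against the scanner ratios and read as strain over reference on every array, with correlations between 0.621 and 0.977 to the values computed here. How the authors subtracted background or scaled the arrays is not given in the sources used here. The values were computed from the scanner intensities, and the deposited log2 ratios served as an alternative.

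Each array has 15552 spots in 48 print-tip grids: 12776 gene spots, 1872 external control spots of 14 probes and 904 other control spots. The 12776 gene spots are 6388 probes with 2 spots each. Of these probes, 5326 carried 1 gene symbol, 5324 of which matched the RefSeq table of the S288C assembly R64, which served for names and neighbours only; 58 symbols were updated by the match. The remaining 1062 probes have no name here and appear in counts but in no list. In 15 genes with more than 1 probe, calls differed between the probes for PHO3 in 1 comparison and for PRM7 in 3.

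Background was subtracted with normexp (offset 50), and log2 ratios were scaled within each array by lowess (span 0.4, 3 robust iterations) over the gene spots, which sets the typical gene to 0. Ratios were turned to strain over reference and averaged over the 2 spots of a probe. One linear model with a mean per strain was fitted to the 16 arrays in limma 3.58.1 under R 4.3.3 (8 residual degrees of freedom, 2.57 prior degrees of freedom), and 18 contrasts were taken from it: each strain against the reference, 3 truncations against 1:713, cdk8-del in each of 3 truncations and on average, and the 3 differences between those effects. A probe was called at a Benjamini-Hochberg adjusted p under 0.01 and a fold above 1.7, the limits that the series description gives without saying whether its p is adjusted. The tests are two-sided. Figures were drawn in matplotlib 3.10.9 with pandas 2.3.3 under Python 3.11.15.

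Gene lists of 4 to 128 members, 33 in all, were written from general knowledge of yeast regulons, and 26 of their 892 entries had no probe. Each list was tested in each contrast with limma's camera, at the preset correlation of 0.01 and with an estimated correlation, with adjustment over the 594 pairs of list and contrast. Members called were counted with adjustment over all probes and adjusted over the list alone. At the preset correlation 213 pairs had an adjusted p under 0.05, with an estimated correlation 14, with the replicate letter as a block 210 and with both 2, the proteasome list in 1:609 and in 1:594 against 1:713 (adjusted p 0.05 in each when rounded). Both p-values are given beside each list, and the third where the second is under 0.05.

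Named genes were chosen by a rule: the 5 largest rises and 5 largest falls among called genes whose arrays do not overlap (10 and 10 for the cdk8-del average and for 1:594 against the reference), up to 3 called members of each list, and FCP1, SSN3, SSN8, SRB8 and SSN2 always. A gene named in 1 comparison could be given in another. For a probe not above background (3 background standard deviations) on any array of a side, a bound on the fold is given in place of the fold.

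Arrays with the same letter resembled each other: with the strain means removed, each of the 16 correlated best, among the arrays of other strains, with one of its own letter. The a and b deviations of a strain are then mirror images, so the 2 arrays of a strain are not separate results. With the strain means kept, and with the other array of the same strain included, 14 of 16 correlated best with an array of their own letter. Letter and dye orientation coincide, so the blocked fit removes both. It kept every call of the unblocked fit and is given beside counts that moved by more than 1.5 times. The pipeline was tested on simulated data with gene-specific dye effects and 50 probes changed at each of 4 folds. In the average over the truncations, 48 of 50 probes changed by 2 fold were called and 0 of 6188 unchanged ones; in the difference between 1:594 and 1:666, 27 of 50 were, or 46 of 50 and 0 unchanged ones with the replicate letter as a block. Without dye effects it was 29 of 50 by either fit. In 1:594 against 1:713, 4 of 6188 unchanged probes were called by either fit without dye effects, and 0 with them. The median standard error was 0.082 against the reference, 0.12 for differences between strains, 0.067 for the cdk8-del average and 0.16 for differences of differences, and the number of arrays limits the precision.

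The groups, contrasts, thresholds, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives tried were no background subtraction, plain subtraction, median centring in place of lowess, lowess within print-tip grids, lowess on the external control spots, the deposited log2 ratios, leaving out the 20% dimmest probes, the replicate letter as a block, an intensity trend with a robust prior, an unadjusted p under 0.01, an adjusted p under 0.05 at any fold, and each array left out in turn. After seeing the data, a fit without the 4 arrays of fcp1-mut and 1:713 and the block together with an estimated correlation were added. No array was left out of the values reported, no probe was filtered, and no sample remained outside the groups.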

Results

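Gene expression was measured in budding yeast on 16 spotted arrays, 2 for each of 8 strains. FCP1 encodes the phosphatase that removes phosphates from the C-terminal domain of RNA polymerase II, and SSN3, also called CDK8, encodes the kinase of the Mediator complex. Per the labels, 1 strain carried an allele named fcp1-mut, whose change is not given in the sources used here. Another 4 carried truncations of FCP1 named 1:713, 1:666, 1:609 and 1:594, and the last 3 carried 1:666, 1:609 or 1:594 together with cdk8-del. The labels read fcp1-mut-tag-flag, fcp1-trunc-1:713-tag-flag and so on, with +cdk8-del added for the last 3, and are shortened here. Every FCP1 allele was labelled as tagged with FLAG, and no oxidant or other treatment is named for any culture. Each array set 1 strain against a common reference pool, whose genotype is not given in the sources used here. The strain was in Cy3 on the arrays lettered a and in Cy5 on those lettered b. The median spot signal lay between 292 and 1058 for the strains and between 211 and 974 for the reference, over local backgrounds of 41 to 72, and 96.4% to 98.8% of the gene probes were above background in the strain. All changes below are log2 ratios with the standard error of limma over n = 2 arrays per strain, relative to the typical gene on the array. A gene was called at an adjusted p under 0.01 and a fold above 1.7. The a and b arrays are not stated to come from separate cultures, so the p-values measure the spread between arrays only.

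The genes altered by the genotypes were examined first. The FCP1 transcript (YMR277W) was called lower against the reference in each of the 4 strains with 1:609 or 1:594, at -3.49 ± 0.14 in 1:609, -2.77 ± 0.14 in 1:594, -3.19 ± 0.14 in 1:609 cdk8-del and -3.43 ± 0.14 in 1:594 cdk8-del, on 8 of 8 arrays. In fcp1-mut, 1:713, 1:666 and 1:666 cdk8-del it was not called, at -0.20, -0.31, -0.27 and -0.27. Where in FCP1 the probe lies is not given in the sources used here, so a loss of signal and a loss of the probed sequence cannot be told apart. SSN3 (YPL042C) was not above background on any of the 6 cdk8-del arrays, which puts it at least 2.32-fold lower than the reference in 1:666 cdk8-del, at least 3.11-fold lower in 1:609 cdk8-del and at least 3.51-fold lower in 1:594 cdk8-del. In the 5 strains with CDK8 it was not called, between -0.15 and 0.062. SSN8, SRB8 and SSN2, which encode the other members of the kinase module, were not called in any strain, between -0.15 for SSN2 in 1:609 and 0.16 for SSN8 in 1:666 cdk8-del. A pair of auxotrophic marker genes separated the strains in another way. MET17, needed for methionine synthesis, was called lower in 6 strains, between -4.92 in 1:609 and -4.51 in 1:666, but was at -0.051 in 1:666 cdk8-del and -0.44 in 1:594 cdk8-del. LYS2, needed for lysine synthesis, was called higher in the same 4 strains as those with low FCP1, from 2.73 in 1:594 to 3.40 in 1:609, and lay between -0.10 and 0.12 in the other 4.

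**Figure D1:**
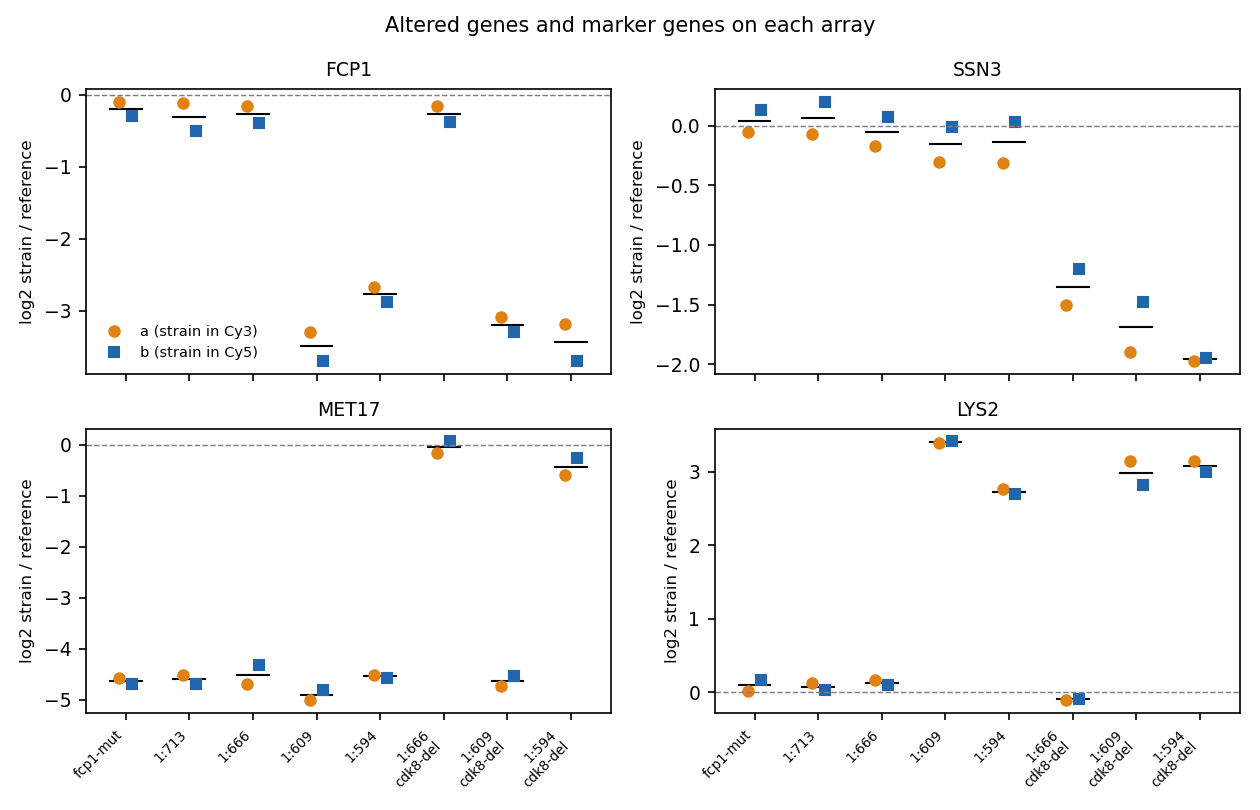
Log2 ratio of strain to reference on each array for FCP1, SSN3, MET17 and LYS2 in the 8 strains; circles are a arrays (strain in Cy3), squares are b arrays (strain in Cy5) and lines are means. As strain means, FCP1 lies between -2.77 and -3.49 in the 4 strains with 1:609 or 1:594, where LYS2 lies between 2.73 and 3.40. MET17 is near the reference in 1:666 cdk8-del and 1:594 cdk8-del.

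The strains fcp1-mut and 1:713 were compared with the reference. The genotype of the pool is not given and its RNA was isolated by another protocol, so any comparison with it holds differences in strain background and isolation along with those of the allele. In fcp1-mut, NCE103, encoding carbonic anhydrase, rose by 1.80 ± 0.11. The falls included MET17 (-4.63 ± 0.11), the phosphate transporter gene PHO84 (-1.91 ± 0.066) and ASP3-3, encoding an asparaginase (-1.73 ± 0.064). In 1:713 the same 4 genes were called in the same directions: NCE103 at 1.66 ± 0.11, MET17 at -4.60 ± 0.11, PHO84 at -1.51 ± 0.066 and ASP3-3 at -1.66 ± 0.064. PRM15, encoding a phosphoribomutase, rose in both (1.13 ± 0.074 and 1.07 ± 0.074), as did YJR154W, a gene without an assigned role (0.97 ± 0.072 and 0.90 ± 0.072). Scaled on the external control spots, PRM15 lost both calls (0.38 and 0.59) and so did YJR154W (0.23 and 0.43). YJR154W in 1:713 also lost its call under median centring (0.90). The phosphate regulon list had 1 of 18 members called lower (1 lower adjusted over the list alone) in fcp1-mut. Its median was -0.086 (camera adjusted p = 0.000116, or 0.0575 with an estimated correlation). In 1:713 it had 1 of 18 members called lower (1 lower adjusted over the list alone). Its median was -0.12 (camera adjusted p = 3.74e-06, or 0.0356 with an estimated correlation and 0.0657 with that and the replicate letter as a block). Scaled on the external control spots, the adjusted p was 0.61 in fcp1-mut and 0.302 in 1:713. In all, limma called 15 probes in fcp1-mut (8 higher, 7 lower) and 11 in 1:713 (4 higher, 7 lower). With the replicate letter as a block these counts were 23 and 18. Scaled on the external control spots, they were 3240 (1 higher, 3239 lower) and 310 (1 higher, 309 lower), as that scaling lowered the typical gene against the reference in each strain. Plain background subtraction gave 18 in 1:713. PHO84 was the only probe called in the same direction in all 8 strains, from -3.0 in 1:594 cdk8-del to -1.51 in 1:713.

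The strain with the next shorter allele, 1:666, was compared with the reference and with 1:713. Against the reference, YRO2, encoding a plasma membrane protein related to a heat shock protein, fell by 2.32 ± 0.16, and so did CHA1, encoding a serine and threonine deaminase (-1.90 ± 0.073), and ARG3, of arginine synthesis (-0.92 ± 0.060). NCE103 rose by 2.23 ± 0.11 and PYC1, encoding pyruvate carboxylase, by 1.53 ± 0.11. Against 1:713, limma called CHA1 lower, at -1.41 ± 0.10 (adjusted p = 0.00031), lower on both 1:666 arrays than on both 1:713 arrays. Under median centring it was not called, at -1.37 (adjusted p = 0.157). YRO2 at -2.01 ± 0.22 and GCV1, of the glycine cleavage complex, at -0.85 ± 0.085 were called as well, with adjusted p-values of 0.00634 and 0.00322, and not under median centring (-1.98 and -0.86). YRO2 also lost its call with print-tip lowess (-2.02), and GCV1 when scaled on the external control spots (-0.90). Neither call survived the omission of any 1 of the 4 arrays. Without 1:666 a, 1:666 b, 1:713 a or 1:713 b in turn, YRO2 stood at -1.81, -2.21, -2.02 and -2.0 (adjusted p 0.1, 0.0253, 0.1 and 0.0479). Likewise GCV1 stood at -0.78, -0.93, -0.79 and -0.91 (adjusted p 0.0469, 0.0151, 0.0732 and 0.0141). As a set, the methionine and sulfate assimilation genes ranked higher in 1:666 than in 1:713. Limma gave 0 of 30 members called (0 adjusted over the list alone, 11 higher and 1 lower at an unadjusted p under 0.05) in that list. Its median was 0.17 (camera adjusted p = 2.73e-08, or 0.0298 with an estimated correlation and 0.146 with that and the replicate letter as a block). The proteasome list also ranked higher, with 0 of 36 members called (0 adjusted over the list alone, 10 higher and 1 lower at an unadjusted p under 0.05). Its median was 0.16 (camera adjusted p = 2.66e-05, or 0.0356 with an estimated correlation and 0.146 with that and the replicate letter as a block). The Msn2/Msn4 general stress list, targets of the transcription factors of the environmental stress response, ranked lower in 1:666 than in 1:713. It had 0 of 40 members called (1 lower adjusted over the list alone, 0 higher and 11 lower at an unadjusted p under 0.05) with limma. Its median was -0.25 (camera adjusted p = 2.13e-07, or 0.517 with an estimated correlation). The counts were 40 probes against the reference (8 higher, 32 lower) and 3 against 1:713, or 12 with the replicate letter as a block. The first count was 77 with plain background subtraction, 23 under median centring and 974 (2 higher, 972 lower) when scaled on the external control spots. The second was 9 with plain background subtraction, and under median centring limma called 0 (224 at an unadjusted p under 0.05). Without 1:666 a the first count was 21, and without any 1 of the 4 arrays the second was 1.

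The 1:609 strain was compared with 1:713. Raised LYS2 marks every 1:609 and 1:594 strain and none of the others, so these comparisons do not separate the truncation from another difference in strain background. Against 1:713, LYS2 rose by 3.32 ± 0.10, SER3, of serine synthesis, by 2.63 ± 0.27 and HPF1, encoding a cell wall mannoprotein, by 2.01 ± 0.17. MF(ALPHA)2, encoding the alpha-factor pheromone, fell by 3.98 ± 0.21, FCP1 stood at -3.18 ± 0.20 and YRO2 at -2.93 ± 0.22, each lower on both 1:609 arrays than on both 1:713 arrays. The other alpha-specific genes went the same way, such as SAG1, encoding alpha-agglutinin (-2.07 ± 0.14), and STE3, encoding the receptor for a-factor (-1.95 ± 0.10). The alpha-specific list had 4 of 4 members called lower (4 lower adjusted over the list alone). Its median was -2.01 (camera adjusted p = 2.71e-07, or 0.039 with an estimated correlation and 0.167 with that and the replicate letter as a block). Under median centring SAG1 (-1.90) and STE3 (-1.78) were no longer called, while MF(ALPHA)2 was. The a-specific list had 0 of 7 members called (0 adjusted over the list alone, 0 higher and 0 lower at an unadjusted p under 0.05) with limma. Its median was 0.12 (camera adjusted p = 0.468, or 0.868 with an estimated correlation). BNA5 (-1.39 ± 0.15), BNA1 (-1.13 ± 0.11) and BNA4 (-0.92 ± 0.11), each encoding an enzyme of NAD synthesis from tryptophan, were called lower, as was PHO84 (-1.03 ± 0.094). The NAD, thiamine and biotin synthesis list had 5 of 25 members called lower (5 lower adjusted over the list alone). Its median was -0.15 (camera adjusted p = 0.00215, or 0.348 with an estimated correlation). The proteasome list ranked higher, though limma gave 0 of 36 members called (0 adjusted over the list alone, 27 higher and 0 lower at an unadjusted p under 0.05). Its median was 0.40 (camera adjusted p = 1.44e-11, or 0.0107 with an estimated correlation and 0.05 with that and the replicate letter as a block). The Hsf1 heat shock list, targets of the heat shock factor, had 2 of 27 members called higher (2 higher adjusted over the list alone). Its median was 0.43 (camera adjusted p = 8.91e-07, or 0.193 with an estimated correlation). The drug transport list had 2 of 20 members called lower (2 lower adjusted over the list alone). Its median was -0.33 (camera adjusted p = 0.000112, or 0.0513 with an estimated correlation). For the Gcn4 list of amino acid synthesis genes the median was -0.039 and the mean 0.12, and limma with camera gave adjusted p = 0.36, or 0.732 with an estimated correlation. It had 4 of 44 members called higher (4 higher adjusted over the list alone). Limma called 126 probes against 1:713 (32 higher, 94 lower) and 199 against the reference (46 higher, 153 lower). Under median centring the first count was 49, with plain background subtraction the counts were 206 and 328, and scaled on the external control spots they were 77 (6 higher, 71 lower) and 2422 (9 higher, 2413 lower).

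The strain with the shortest allele, 1:594, was compared with the reference and with 1:713. Against the reference, LYS2 rose by 2.73 ± 0.072, NCE103 by 2.48 ± 0.11, HPF1 by 2.24 ± 0.12 and SER3 by 2.04 ± 0.19. The falls included MF(ALPHA)2 (-4.01 ± 0.15), YRO2 (-2.81 ± 0.16), CHA1 (-2.55 ± 0.073), YHB1, encoding flavohemoglobin (-2.37 ± 0.073), and GCV2, of the glycine cleavage complex (-1.88 ± 0.11), each in the same direction on both arrays. Against 1:713, LYS2 stood at 2.65 ± 0.10, MF(ALPHA)2 at -3.76 ± 0.21, CHA1 at -2.06 ± 0.10, FCP1 at -2.46 ± 0.20, PHO84 at -1.09 ± 0.094, BNA1 at -1.05 ± 0.11 and SNZ3, of vitamin B6 and thiamine synthesis, at -1.0 ± 0.092. The alpha-specific list again had 4 of 4 members called lower (4 lower adjusted over the list alone). Its median was -1.85 (camera adjusted p = 2.73e-08, or 0.034 with an estimated correlation and 0.146 with that and the replicate letter as a block). The a-specific list had 0 of 7 members called (0 adjusted over the list alone, 0 higher and 0 lower at an unadjusted p under 0.05) with limma. Its median was 0.045 (camera adjusted p = 0.886, or 0.978 with an estimated correlation). The proteasome list ranked higher as in 1:609, and limma gave 0 of 36 members called (0 adjusted over the list alone, 25 higher and 0 lower at an unadjusted p under 0.05). Its median was 0.38 (camera adjusted p = 1.51e-12, or 0.0107 with an estimated correlation and 0.05 with that and the replicate letter as a block). The Hsf1 list had 2 of 27 members called higher (2 higher adjusted over the list alone). Its median was 0.49 (camera adjusted p = 2.5e-09, or 0.13 with an estimated correlation). Among drug transport genes there were 0 of 20 members called (0 adjusted over the list alone, 0 higher and 12 lower at an unadjusted p under 0.05) with limma. Their median was -0.30 (camera adjusted p = 0.000124, or 0.0513 with an estimated correlation). For NAD, thiamine and biotin synthesis there were 3 of 25 members called lower (3 lower adjusted over the list alone). Their median was -0.13 (camera adjusted p = 0.00169, or 0.335 with an estimated correlation). Limma called 144 probes against the reference (42 higher, 102 lower) and 81 against 1:713 (27 higher, 54 lower), the latter 37 under median centring. With plain background subtraction the counts were 275 and 154, and scaled on the external control spots they were 1182 (10 higher, 1172 lower) and 33 (9 higher, 24 lower). Of the probes called against 1:713, 19 were higher in both 1:609 and 1:594 and 49 were lower in both. Independent lists of those sizes would share 0.135 and 0.795. The 1:713 arrays are common to both comparisons, so part of the excess may come from them. In 100 simulations with that shared error and no effects limma called no probe for 1:609, so their overlaps of 0 and 0 say nothing about that part. Across genes, which are not independent replicates, the changes in 1:609 and 1:594 against 1:713 correlated at 0.841, against 0.499 from the shared arrays alone, with a covariance of 0.0768 against 0.0138.

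The study's title concerns oxidative stress, so the genes known for that response were examined as well. GPX2, encoding a glutathione peroxidase, fell against the reference in 1:609, at -1.28 ± 0.12 (adjusted p = 1.84e-05), and in 1:594, at -1.45 ± 0.12 (adjusted p = 1.29e-05), on 4 of 4 arrays. As above, a comparison with the reference holds strain background and isolation along with the allele. Against 1:713, limma called no member of the 2 oxidative stress lists below in 1:666, 1:609 or 1:594. With the replicate letter as a block it called 1 member of each list lower in 1:594, and none in 1:666 or 1:609. In 1:666 limma called GPX2 against the reference at -0.95 ± 0.12, but not without 1:666 a (-0.91, adjusted p = 0.0278) or without 1:666 b (-1.0, adjusted p = 0.0161). With cdk8-del averaged over the 3 truncations, the catalase gene CTT1 rose by 2.94 ± 0.11, the peroxiredoxin gene TSA2 by 1.07 ± 0.071 and SOD2, encoding the mitochondrial superoxide dismutase, by 0.95 ± 0.058, each higher in every truncation. AAD15, an aryl-alcohol dehydrogenase gene, fell by 0.86 ± 0.051, a call that was lost when the arrays were scaled on the external control spots (-0.51). The 31 targets of Yap1 and Skn7, the regulators best known for the response to peroxide, showed no detectable shift as a set. Their medians in the 8 strains against the reference lay between -0.065 and 0.055, and the lowest camera adjusted p was 0.24, or 0.422 with an estimated correlation. Against 1:713, limma gave 0 of 31 members called (0 adjusted over the list alone, 1 higher and 3 lower at an unadjusted p under 0.05) in 1:666. In 1:609 there were 0 of 31 members called (0 adjusted over the list alone, 2 higher and 8 lower at an unadjusted p under 0.05). The 1:594 allele gave 0 of 31 members called (1 lower adjusted over the list alone, 3 higher and 6 lower at an unadjusted p under 0.05). In 1:609 the median was 0.024, the mean -0.018 and the camera adjusted p 0.905 with limma, or 0.969 with an estimated correlation. For cdk8-del on average there were 1 of 31 members called higher and 1 lower (1 higher and 1 lower adjusted over the list alone). The median was -0.020 and the mean 0.042, and limma's camera gave adjusted p = 0.926, or 0.976 with an estimated correlation. The list of 30 antioxidant enzymes ranked higher with cdk8-del on average, with 3 of 30 members called higher (3 higher adjusted over the list alone). Its median was 0.18 (camera adjusted p = 0.00111, or 0.219 with an estimated correlation). Its member CTT1 is also in the Msn2/Msn4 list. Against 1:713 the antioxidant list gave camera adjusted p-values of 0.592 in 1:666, 0.289 in 1:609 and 0.475 in 1:594, or 0.854, 0.701 and 0.813 with an estimated correlation. Limma gave 0 of 30 members called (0 adjusted over the list alone, 0 higher and 2 lower at an unadjusted p under 0.05) in 1:666. In 1:609 there were 0 of 30 members called (0 adjusted over the list alone, 3 higher and 3 lower at an unadjusted p under 0.05). The 1:594 allele gave 0 of 30 members called (0 adjusted over the list alone, 2 higher and 3 lower at an unadjusted p under 0.05).

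The change with cdk8-del was then examined in the 3 truncation strains. No strain here has cdk8-del without 1 of these truncations. An effect of losing CDK8 in any strain and one that depends on a truncated allele therefore cannot be told apart. Averaged over the 3, YGP1, encoding a stress-induced cell wall protein, rose by 3.54 ± 0.11, YRO2 by 3.39 ± 0.13, RTC3 by 3.18 ± 0.13 and the small heat shock gene HSP26 by 3.0 ± 0.15. Of the Msn2/Msn4 list, which also holds YGP1 and HSP26, GPH1, encoding glycogen phosphorylase, rose by 2.93 ± 0.14, HXK1, encoding hexokinase, by 2.90 ± 0.16 and ALD3, encoding an aldehyde dehydrogenase, by 2.62 ± 0.083. NCE103 fell by 2.0 ± 0.089 and the biotin synthesis genes BIO3, BIO4, BIO2 and BIO5 stood at -1.67 ± 0.085, -1.62 ± 0.11, -1.48 ± 0.080 and -1.44 ± 0.14. The Msn2/Msn4 general stress list had 33 of 40 members called higher (33 higher adjusted over the list alone). Its median was 1.48 (camera adjusted p = 4.09e-37, or 0.13 with an estimated correlation). The respiration and TCA cycle list had 12 of 49 members called higher (12 higher adjusted over the list alone), led by CYC7, encoding cytochrome c, at 1.76 ± 0.092. The list median was 0.55 (camera adjusted p = 4.42e-20, or 0.154 with an estimated correlation). The stationary phase list, which shares 6 genes with the Msn2/Msn4 list, had 13 of 25 members called higher (13 higher adjusted over the list alone). Its median was 0.88 (camera adjusted p = 9.02e-12, or 0.302 with an estimated correlation). Among the cell wall integrity genes GSC2, encoding a glucan synthase, rose by 1.49 ± 0.051 and CWP1 by 2.42 ± 0.14. That list had 5 of 21 members called higher (5 higher adjusted over the list alone). Its median was 0.26 (camera adjusted p = 4.7e-06, or 0.107 with an estimated correlation). The ribosome biogenesis list ranked lower, though limma gave 0 of 79 members called (0 adjusted over the list alone, 0 higher and 60 lower at an unadjusted p under 0.05). Its median was -0.29 (camera adjusted p = 1.15e-15, or 0.0699 with an estimated correlation). The Gcn4 list also ranked lower, with 2 of 44 members called higher and 1 lower (2 higher and 1 lower adjusted over the list alone), while its member ARG3 rose by 1.64 ± 0.049. Its median was -0.26 (camera adjusted p = 2.32e-09, or 0.0599 with an estimated correlation). PUT4, encoding a proline permease, was at background in the truncation strains and at least 3.29-fold higher with cdk8-del, a call lost under median centring (1.73). In all, limma called 173 probes (149 higher, 24 lower), or 358 (346 higher, 12 lower) when scaled on the external control spots.

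**Figure D2:**
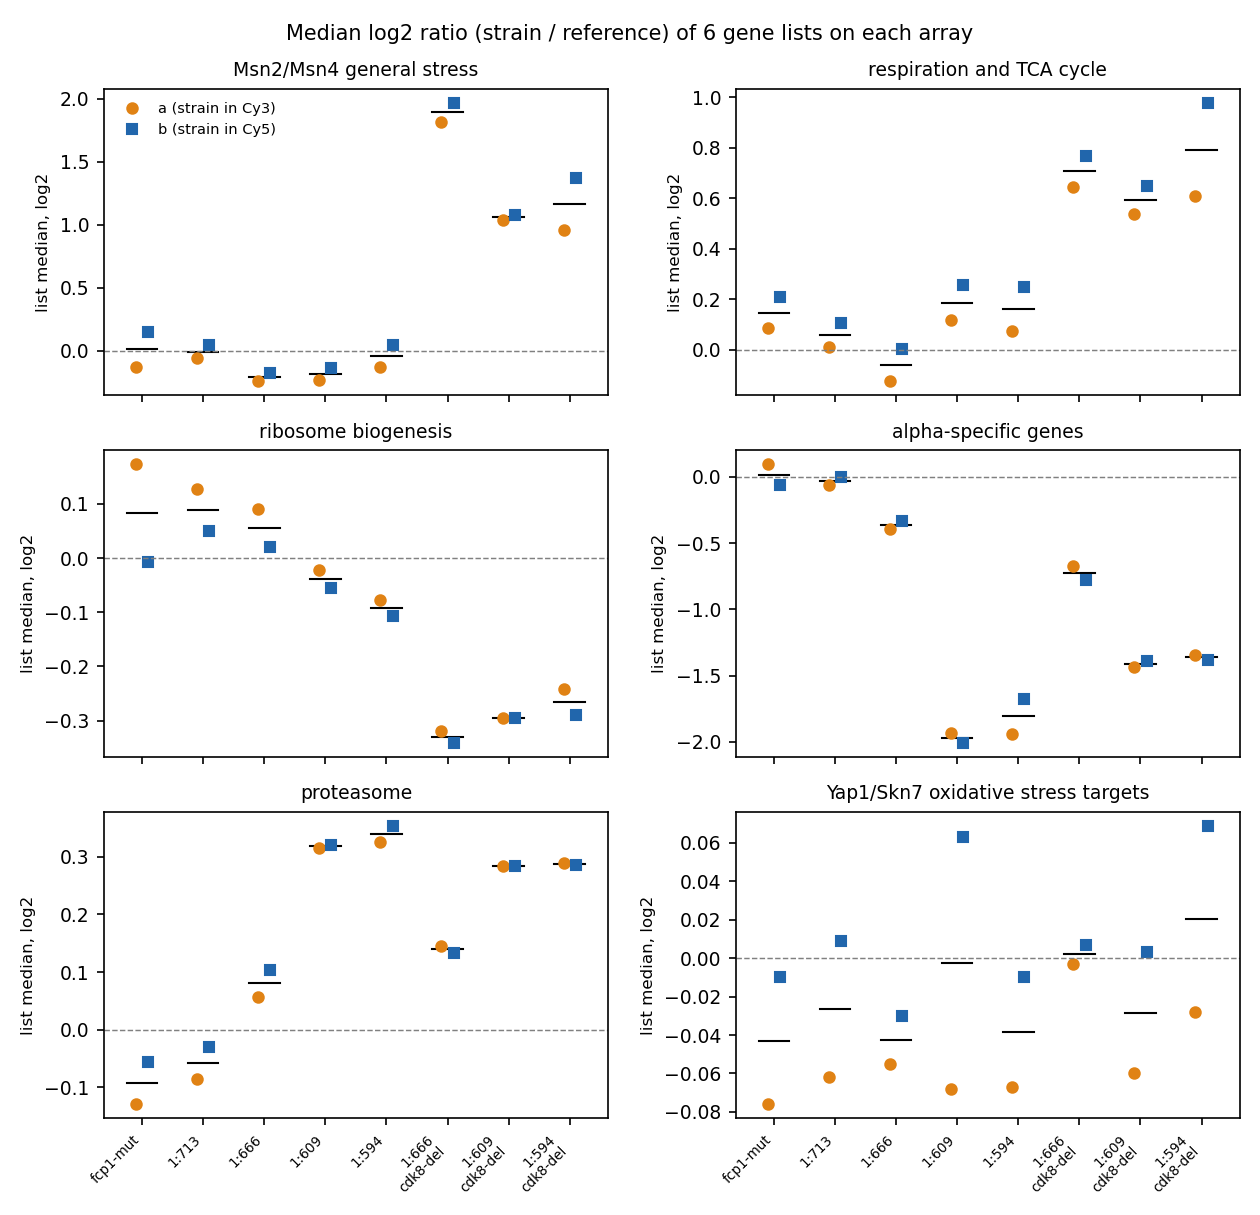
Median log2 ratio of strain to reference over the members of 6 gene lists on each of the 16 arrays; circles are a arrays (strain in Cy3) and squares are b arrays (strain in Cy5). The Msn2/Msn4 list lies highest in 1:666 cdk8-del, with a strain median of 1.91, against 1.04 in 1:609 cdk8-del and 1.15 in 1:594 cdk8-del.

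In each truncation taken alone, many of the same genes were higher with cdk8-del, though only in 1:609 were the strains compared alike in MET17. CTT1 rose by 3.89 ± 0.19 in 1:666, 2.46 ± 0.19 in 1:609 and 2.48 ± 0.19 in 1:594, RTC3 by 3.92 ± 0.22, 2.82 ± 0.22 and 2.80 ± 0.22, and the heat shock gene SSA4 by 1.57 ± 0.10, 1.12 ± 0.10 and 0.96 ± 0.10. NCE103 fell in each, at -2.13, -2.12 and -1.75. MET17 differed by 4.46 ± 0.15 in 1:666 and 4.10 ± 0.15 in 1:594, where the cdk8-del strain was near the reference and the strain with CDK8 was low, and stood at 0.28 ± 0.15 in 1:609, where it was not called. The Msn2/Msn4 list had 37 of 40 members called higher (37 higher adjusted over the list alone) in 1:666. Its median was 2.11 (camera adjusted p = 1.4e-46, or 0.105 with an estimated correlation). In 1:609 it had 26 of 40 members called higher (29 higher adjusted over the list alone). Its median was 1.25 (camera adjusted p = 7.07e-42, or 0.117 with an estimated correlation). In 1:594 it had 26 of 40 members called higher (29 higher adjusted over the list alone). Its median was 1.24 (camera adjusted p = 1.87e-36, or 0.13 with an estimated correlation). Respiration genes ranked higher in each, with 21 of 49 members called higher (25 higher adjusted over the list alone) in 1:666. Their median was 0.78 (camera adjusted p = 8.38e-22, or 0.14 with an estimated correlation). In 1:609 there were 2 of 49 members called higher (2 higher adjusted over the list alone). Their median was 0.35 (camera adjusted p = 9.24e-14, or 0.221 with an estimated correlation). In 1:594 there were 10 of 49 members called higher (13 higher adjusted over the list alone). Their median was 0.54 (camera adjusted p = 8.66e-21, or 0.152 with an estimated correlation). In 1:609, limma called MF(ALPHA)2 higher with cdk8-del, at 1.48 ± 0.21, though not without 1:609 a (1.30, adjusted p = 0.0225), without 1:609 cdk8-del b (1.17, adjusted p = 0.0141) or under median centring (1.36). Limma called 255 probes in 1:666 (211 higher, 44 lower), 104 in 1:609 (87 higher, 17 lower) and 137 in 1:594 (107 higher, 30 lower). With the replicate letter as a block the count in 1:609 was 169, and under median centring the counts were 107, 52 and 41. Scaled on the external control spots, they were 368 (359 higher, 9 lower), 258 (255 higher, 3 lower) and 88 (76 higher, 12 lower). Leaving out 1:609 cdk8-del a took the count in 1:609 to 66, and leaving out 1:594 a or 1:594 cdk8-del b took that in 1:594 to 80 or 87. Of 225 probes called higher in at least 1 truncation 75 were called in all 3, and of 56 called lower 14 were.

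The double mutants were compared with the reference as well. Each such change is the sum of the truncation's change and the cdk8-del change from the same arrays, so it holds both by construction. In 1:666 cdk8-del, HSP12, encoding a membrane-protecting stress protein, rose by 3.86 ± 0.19, CTT1 by 3.65 ± 0.14, HSP26 by 3.58 ± 0.18 and ALD3 by 3.49 ± 0.10, and PHO84 (-2.60 ± 0.066) and YHB1 (-2.13 ± 0.073) fell. In 1:609 cdk8-del, LYS2 rose by 2.98 ± 0.072, HSP12 by 2.85 ± 0.19 and CTT1 by 2.75 ± 0.14, and MF(ALPHA)2 fell by 2.76 ± 0.15. In the strain 1:594 cdk8-del, LYS2 rose by 3.07 ± 0.072, HSP12 by 3.01 ± 0.19 and HSP30 by 2.91 ± 0.29, and MF(ALPHA)2 (-2.88 ± 0.15) and CHA1 (-2.51 ± 0.073) fell. The alpha-specific list had 4 of 4 members called lower (4 lower adjusted over the list alone) in 1:609 cdk8-del. Its median was -1.35 (camera adjusted p = 7.25e-05, or 0.0699 with an estimated correlation). In 1:594 cdk8-del it had 4 of 4 members called lower (4 lower adjusted over the list alone). Its median was -1.31 (camera adjusted p = 7.4e-05, or 0.0699 with an estimated correlation). Limma called 250 probes in 1:666 cdk8-del (191 higher, 59 lower), 238 in 1:609 cdk8-del (116 higher, 122 lower) and 292 in 1:594 cdk8-del (164 higher, 128 lower). Scaled on the external control spots, the counts were 345 (125 higher, 220 lower), 365 (63 higher, 302 lower) and 779 (54 higher, 725 lower), so in 1:666 cdk8-del and 1:594 cdk8-del the majority turned from higher to lower. Plain background subtraction gave 383 in the first and 390 in the second.

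**Figure D3:**
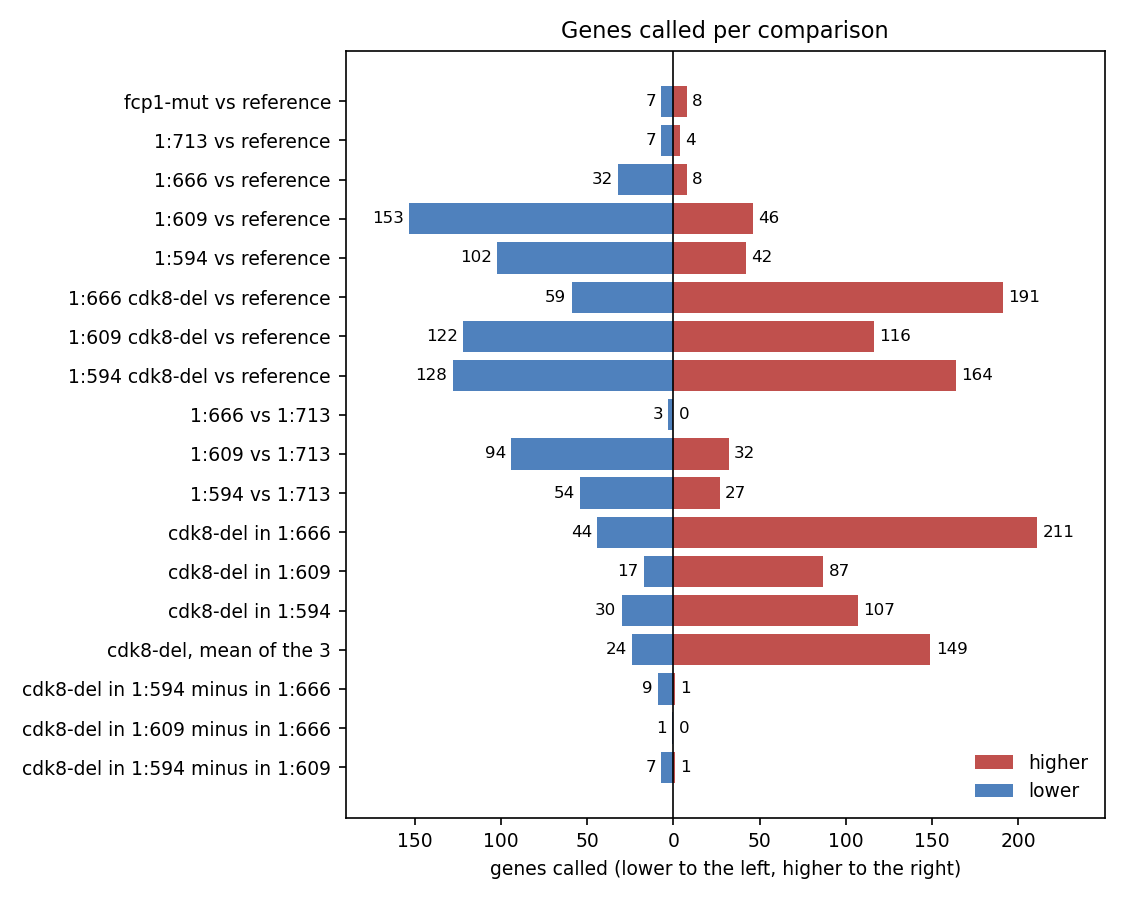
Number of probes called higher and lower in each comparison at an adjusted p under 0.01 and a fold above 1.7. The counts against the reference run from 11 in 1:713 to 292 in 1:594 cdk8-del, and cdk8-del called 255 in 1:666, 104 in 1:609 and 137 in 1:594.

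Whether the effect of cdk8-del differed between truncations was tested as a difference of differences. Limma called MET17, at -4.18 ± 0.21 in 1:609 minus 1:666 (adjusted p = 6.69e-06) and 3.83 ± 0.21 in 1:594 minus 1:609 (adjusted p = 1.66e-05). The Msn2/Msn4 list rose less in 1:609 and 1:594 than in 1:666, with a median difference of -0.88 (camera adjusted p = 2.59e-44, 0.113 with an estimated correlation) and -0.90 (camera adjusted p = 1.15e-43, 0.116 with an estimated correlation). Within that list, limma gave 0 of 40 members called (17 lower adjusted over the list alone, 0 higher and 34 lower at an unadjusted p under 0.05) in the first. In the second there were 2 of 40 members called lower (20 lower adjusted over the list alone). With limma FCP1 was not called in any of the 3 differences, the largest being -0.96 ± 0.28 in 1:594 minus 1:609 (adjusted p = 0.547). It was called there with the replicate letter as a block (adjusted p = 0.00109). In all, limma called 10 probes for 1:594 minus 1:666, 1 for 1:609 minus 1:666 and 8 for 1:594 minus 1:609, against 48, 45 and 13 with the replicate letter as a block. Of these, 7 of the 10 and 7 of the 8 are ASP3-3, YLR161W, which lies near it on chromosome XII, and 5 unnamed probes with probe numbers next to theirs. In these 7 probes 1:594 lay above each of the other 7 strains, by at least 0.55. The 3 cdk8-del strains lay within 0.30 of each other, so these calls rest on the level in 1:594. A peculiarity of that strain and an effect of cdk8-del present only in 1:594 cannot be told apart. The 1 in 1:609 minus 1:666 and the remaining 1 of the 8 is MET17, and the remaining 3 of the 10 are ALD3, TPS2 and YHB1. Under median centring limma called 0 (162 at an unadjusted p under 0.05), 1 and 3. Leaving out 1:594 a took the number of different probes called in any of the 3 from 11 to 6, and leaving out 1:594 cdk8-del a or 1:594 cdk8-del b took it to 18 or 28.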

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

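Of the tests in this part, the regroupings of the arrays that count called probes were planned, and the regroupings for the list's median, the contrast of 1:594 with 1:609 and the tests of marker genes, growth phase, mating type, ploidy, starting level and strain background were chosen only after the results were seen. With 2 arrays per strain, no test for a single outlying array applied.

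A test with limma of whether the effect of cdk8-del differed between truncations called 10 probes in 1:594 minus 1:666, 1 probe in 1:609 minus 1:666 and 8 probes in 1:594 minus 1:609. Of these, 7 of the 10 and 7 of the 8 are ASP3-3, YLR161W and 5 unnamed probes with probe numbers next to theirs. All 7 were also called in 1:594 against 1:609 without cdk8-del, 1:594 lay above each of the other 7 strains in them by at least 0.55, and the 3 cdk8-del strains lay within 0.30 of each other. Those calls therefore rest on the level in the 1:594 strain, where ASP3-3 stood at -0.46, against -1.75 in 1:594 cdk8-del. A peculiarity of that strain and an effect of cdk8-del present only in 1:594 cannot be told apart. The remaining calls are ALD3, TPS2 and YHB1 in the first difference and MET17, a marker gene, in the other 2. In 1:594 minus 1:666, ALD3, encoding an aldehyde dehydrogenase, differed by a log2 of -1.64 (SE 0.203, adjusted p = 0.00546), ASP3-3, encoding an asparaginase, by -1.33 (SE 0.129, adjusted p = 0.00144), TPS2, of trehalose synthesis, by -1.30 (SE 0.128, adjusted p = 0.00144), YLR161W by -1.02 (SE 0.109, adjusted p = 0.00237) and YHB1, encoding flavohemoglobin, by 1.14 (SE 0.146, adjusted p = 0.00643). The 5 calls were lost when scaled on the external control spots (ALD3 -1.83, ASP3-3 -1.68, TPS2 -1.51, YLR161W -0.88 and YHB1 0.87, adjusted p 0.0215 to 0.385), under median centring (-1.61, -1.33, -1.29, -0.91 and 1.15 in the same order, adjusted p 0.0132 to 1) and in the fit without the 4 arrays of fcp1-mut and 1:713 (adjusted p 0.0122 to 0.031), where the differences are the same as in the full fit and only the adjusted p moved, and those of YHB1 and YLR161W also without background subtraction (1.16 and -0.98, adjusted p 0.0107 and 0.0163). Leaving out single arrays ended calls as well. ALD3 was not called without any 1 of 7 of the 8 arrays, the exception being 1:594 cdk8-del b (-1.42 to -1.73, adjusted p 0.0171 to 0.0398 without the others), and YHB1 not without any 1 of 7, the exception being 1:666 a (1.03 to 1.23, adjusted p 0.0112 to 0.0443). ASP3-3 was not called without 1:666 cdk8-del b (-1.26, adjusted p = 0.0114) or 1:666 b (-1.31, 0.015), and TPS2 not without either of those (-1.28, 0.012, and -1.28, 0.015) or without 1:594 a (-1.28, 0.0115). YLR161W was not called without 1:666 cdk8-del b (-0.97, 0.0172), 1:666 b (-0.99, 0.0195), 1:594 cdk8-del a (-1.02, 0.0171) or 1:594 a (-0.96, 0.0157). In 1:609 minus 1:666 the probe was MET17, at -4.18 (SE 0.211, adjusted p = 6.69e-06). In 1:594 minus 1:609 they included ASP3-3 at -1.44 (adjusted p = 0.000508), YLR161W at -1.10 (adjusted p = 0.00103; -1.08 and 0.0106 without 1:609 a, -1.01 and 0.431 when scaled on the external control spots, -1.15 and 1 under median centring) and MET17 at 3.83 (adjusted p = 1.66e-05). With the replicate letter as a block the counts were 48, 45 and 13, and under median centring limma called 0 (162 at an unadjusted p under 0.05), 1 and 3. As sets, the Msn2/Msn4 list differed by a median of -0.897 in 1:594 minus 1:666 (camera adjusted p = 1.15e-43, 0.116 with an estimated correlation) and -0.882 in 1:609 minus 1:666 (2.59e-44 and 0.113). The methionine and sulfate assimilation list differed by 0.195 in 1:594 minus 1:666 (2.49e-08 and 0.0298, or 0.146 with the block as well). The alpha-specific genes differed by 0.736 in 1:594 minus 1:666 (1.23e-07 and 0.0356, or 0.146 with the block as well) and 0.904 in 1:609 minus 1:666 (6.3e-09 and 0.0298, or 0.146 with the block as well).

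The rise of the Msn2/Msn4 general stress list with cdk8-del is the first pattern weighed. The median of the list was 1.48 on average. Only 1 of 100 regroupings of the 12 arrays within truncations, the real one, gave a median as large in size (highest other 1.16). That is the lowest count possible, and this test of the list was chosen after its rise was seen. Of the other regroupings, 29 held both letters on each side in all 3 truncations. The rest, unlike the real grouping, set 1 letter against the other in at least 1 truncation, and they called at most 1 probe. For the number of called probes, 1 of 100 regroupings reached the real one as well (173, highest other 28), and 1 of 32 with the block (177, highest other 30). These regroupings cover the spread between arrays only, as the a and b arrays are not stated to be separate cultures. Chance differences between cultures are therefore not excluded, and the list had a camera adjusted p of 0.13 with an estimated correlation. The cdk8-del strains of 1:666 and 1:594 also differ in MET17, but in 1:609, where MET17 is alike, the list still rose by a median of 1.25, which argues against that marker as the source. Cultures nearer to stationary phase at harvest remain possible. Ribosome biogenesis genes had a median of -0.293 and ribosomal protein genes one of -0.0412 (-0.369 and -0.0855 under median centring). Per the labels and protocols the strains were grown to mid-log phase, but the density at harvest is not given in the sources used here. The hypothesis that the loss of CDK8 itself raises the list stays open beside that growth difference, which the ribosomal medians did not decide.

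The fall of the alpha-specific genes in 1:609 and 1:594 against 1:713 is the second. Cells of mating type a in the cultures would raise the a-specific genes, whose medians were 0.12 in 1:609 and 0.0452 in 1:594, and the upper quartiles of 0.148 and 0.111 argue against them. Diploid cells would lower the haploid-specific genes as far as the alpha-specific ones (-2.01 and -1.85), but those had medians of -0.486 and -0.306 with lower quartiles of -0.671 and -0.624, although FAR1 at -1.12 and -1.10 was called in both. A strain background shared by these strains cannot be told apart from the truncations, since LYS2 was raised by at least 2.65 in both, although the alpha-specific list was also lower in 2 strains without raised LYS2, with medians of -0.72 in 1:666 cdk8-del (-0.67 and -0.776 on the a and b arrays) and -0.36 in 1:666 (-0.395 and -0.333), against -0.044 in 1:713 (-0.064 and -0.004). The camera adjusted p was 0.00146 in 1:666 cdk8-del and 0.00285 in 1:666 against the reference, or 0.117 and 0.13 with an estimated correlation. LYS2 does not mark these 2 strains, but another difference in background from the reference is not excluded there. Their falls are also smaller than those in 1:609 and 1:594, so they do not exclude the shared background for the larger ones. The hypothesis that the truncations lower the alpha-specific genes therefore stays open beside that shared background, which the LYS2 test did not decide.

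The larger rise of the Msn2/Msn4 list in 1:666 is the third. With an estimated correlation its camera adjusted p was 0.113 for 1:609 minus 1:666 and 0.116 for 1:594 minus 1:666. A lower starting level in 1:666 would leave the cdk8-del strains alike, but 1:666 cdk8-del stood above 1:609 cdk8-del by a median of 0.856 (lower quartile 0.408) and above 1:594 cdk8-del by 0.731 (lower quartile 0.297), while 1:666 itself stood at -0.11 and -0.264 against 1:609 and 1:594. The MET17 difference is present in 1:594 too, where the list rose by less (-0.897, upper quartile -0.579), which argues against it. The strain background cannot be told apart from the truncations here either, as LYS2 was raised by at least 2.73 in every 1:609 and 1:594 strain and in neither 1:666 strain. The hypotheses that 1:609 and 1:594 reduce the response to cdk8-del and that 1:666 enlarges it stay open beside that background. They cannot be told apart, as no strain here has cdk8-del without 1 of these truncations. Beside the starting level, MET17 and that background no other explanation was tested.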

How the results depend on the processing

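Of the settings in this part, the fit without the 4 arrays of fcp1-mut and 1:713 and the block together with an estimated correlation were chosen only after the results were seen. Of the counts of called probes, 127 stayed within 1.5 times under other settings and 60 did not; the cause was not tested except where the setting itself makes it (a laxer threshold or a block). In the order fcp1-mut, 1:713, 1:666, 1:609, 1:594, 1:666 cdk8-del, 1:609 cdk8-del, 1:594 cdk8-del, those that moved were as follows. With plain background subtraction 1:713 had 18, 1:666 77, 1:609 328, 1:594 275, 1:666 cdk8-del 383 and 1:609 cdk8-del 390, and against 1:713 there were 9 in 1:666, 206 in 1:609 and 154 in 1:594. With median centring 1:666 had 23, and against 1:713 limma called 0 in 1:666 (224 at an unadjusted p under 0.05), 49 in 1:609 and 37 in 1:594, while cdk8-del gave 107 in 1:666, 52 in 1:609 and 41 in 1:594 and its differences 3. With lowess on the external control spots the counts were 3240, 310, 974, 2422 and 1182 for the single mutants, 365 for 1:609 cdk8-del, 779 for 1:594 cdk8-del, 77 and 33 for 1:609 and 1:594 against 1:713, 258 and 88 for cdk8-del in 1:609 and 1:594, 358 on average and 4 for its differences. That scaling moved the median of all genes by -0.771, -0.494, -0.548, -0.675, -0.474, -0.156, -0.204 and -0.40 in the 8 strains, by -0.171 in 1:609 against 1:713, by 0.341 and 0.44 for cdk8-del in 1:666 and 1:609, by 0.282 on average and by -0.27 and -0.36 in the differences 1:594 minus 1:666 and 1:594 minus 1:609, so that the falls took most of the calls against the reference (3239 of 3240 in fcp1-mut). It also turned BIO3 in fcp1-mut to -0.036. With the deposited ratios fcp1-mut had 25, 1:713 18, 1:666 against 1:713 11, cdk8-del in 1:609 160 and its differences 62. With the replicate letter as a block these were 23, 18, 12, 169 and 69. With an unadjusted p fcp1-mut had 23, 1:713 19, 1:666 against 1:713 12 and the differences 105. With an adjusted p under 0.05 at any fold the 8 strains had 151, 75, 767, 2165, 1947, 1903, 2173 and 2261, the truncations against 1:713 42, 1118 and 788, cdk8-del 996, 437, 561 and 1704 on average, and the differences 26. Of the 594 list pairs, 14 had an adjusted p under 0.05 with an estimated correlation and 2 with that and the block, against 213. Without 1 array in turn the 8 strains had 10 to 11, 10 to 11, 21 to 28, 181 to 183, 116 to 131, 205 to 241, 188 to 246 and 230 to 316, the truncations against 1:713 1 to 1, 86 to 104 and 60 to 72, cdk8-del 187 to 215, 66 to 72, 80 to 147 and on average 157 to 185, the differences 6 to 28 and the lists 197 to 219. Of the 556 calls of named genes, 551 were kept without background subtraction, 548 with plain subtraction, 317 with median centring, 518 with print-tip lowess, 435 with the external control spots, 527 with the deposited ratios, 556 with the block, 554 with the trend and 525 of 525 without the dimmest probes, and 443 of 457 in the smaller fit; 1 turned its direction. The set tests at an adjusted p under 0.01 were counted once per setting, the estimated correlation not included. Under the other settings 1286 such values stayed under 0.05 and 56 did not. Without 1 array 661 stayed under 0.05 and 17 did not. None of those that stayed turned its direction relative to the typical gene, and the direction of the others was not checked. Threshold and prior settings do not enter camera and give no value for it. Signal over background limits genes such as SSN3 and PUT4 to bounds.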

Other observations

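The contrasts and overlaps in this part were chosen only after the results were seen. PRM15, which lies next to FCP1 in the RefSeq annotation of the R64 assembly, was higher than the reference on every array, between 0.62 and 1.22, and was called in 7 of the 8 strains. DSK2, its neighbour on the other side of FCP1, lay between 0.04 and 0.83 as strain means and was called in 1 strain. ASP3-3 was lower than the reference by log2 ratios from -1.54 to -1.84 in 7 strains but stood at -0.46 in 1:594, and YLR161W lay between -0.46 and -0.80 in 7 strains and at 0.20 in 1:594. In a direct contrast of 1:594 with 1:609, limma called 7 probes, all higher, or 45 with the replicate letter as a block. Among them were ASP3-3 at 1.39 (adjusted p = 2.46e-05), YLR161W at 1.0 (adjusted p = 0.000101) and 5 probes without a name here. A contrast of fcp1-mut with 1:713 gave 0 called probes in limma, 50 at an unadjusted p under 0.05 and 0 with the block.

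Genes called in the truncations and genes called with cdk8-del overlapped in comparisons without shared arrays, in opposite and in like directions. Of the 94 probes called lower in 1:609 against 1:713, 14 were called higher with cdk8-del in 1:594 (1.57 if independent, Fisher's exact p = 3.31e-10, two-sided) and 14 with cdk8-del in 1:666 (3.1 if independent, p = 2.01e-06 by the same exact test). Of the 54 called lower in 1:594 against 1:713, 11 were called higher with cdk8-del in 1:609 (0.735 if independent, exact p = 9.31e-11) and 10 with cdk8-del in 1:666 (1.78 if independent, exact p = 8.38e-06). The 4 overlaps of probes higher in a truncation and lower with cdk8-del held 1 probe each (exact p = 0.14 for 1:609 with cdk8-del in 1:594, 0.0696 for 1:594 with cdk8-del in 1:609, and 0.199 and 0.171 for 1:609 and 1:594 with cdk8-del in 1:666). In like directions, the overlaps with cdk8-del in 1:666 were 5 lower in both for 1:609 (0.647 if independent, exact p = 0.000428) and 4 for 1:594 (0.372 if independent, exact p = 0.000482), and 6 higher in both for 1:609 (1.06 if independent, exact p = 0.000534) and 5 for 1:594 (0.892 if independent, exact p = 0.00167). Between 1:609 and cdk8-del in 1:594 they were 1 lower in both (exact p = 0.36) and 3 higher in both (exact p = 0.0159), and between 1:594 and cdk8-del in 1:609 they were 0 and 2 (exact p = 1 and 0.0517). The overlaps therefore do not show an opposing relation alone. Genes move in groups, so these p-values overstate the evidence, and 26 such overlaps were computed.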
